A study of Drosophila melanogaster and Drosophila melanogaster
Homo sapiens with 19 samples.

How the data were processed

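The series holds 19 samples in 11 groups, all from cultured cells, and 17 deposited tables were analysed. RICh-PET, on bead-captured chromatin (standard) and on chromatin enriched with an RNAPII antibody, had 2 samples each, as had roX2 ChIRP-seq, RNAPII ChIA-PET of S2 cells, and ATAC-seq at each of 0, 200, 400 and 800 µg/ml RNase A. Mixed-cell ChIA-PET had 1 library without RNase A and 1 with 400 µg/ml. The standard and RNAPII RICh-PET libraries also differed in the reverse transcription temperatures, per the labels, so the antibody is not the only difference between these tables. No label says whether samples with different replicate numbers came from separate cultures, so the p-values across libraries measure only the spread between these samples.

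Per the submitters' processing notes the authors used BWA and Picard, both without stated versions, and MACS2 2.0.10, with dm3 and hg19 as the builds. The 2 RICh-PET tables hold values of another kind (other): per the file headers each line is 1 PET with the coordinates of its DNA end, its RNA end and the RNA strand. In the 5 ChIA-PET cluster tables the value is a count, the number of PETs per cluster, deposited as whole numbers from 2 and not scaled to depth; the cluster caller is not stated. In the 10 peak lists (8 ATAC-seq and 2 ChIRP-seq), called per library, the value is a score per peak given by the authors, whose scale is not stated, so scores were used only for ranks and for matching peaks. The 2 RICh-PET tables and the S2 ChIA-PET table pool 2 samples each, and read depths per library were not in the tables, so depth is given as the number of PETs, peaks or clusters. Coordinates were turned into 1-based positions and never moved between builds.

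The main arms were X, 2L, 2R, 3L, 3R and 4; heterochromatic, unplaced and mitochondrial sequences were left out of comparisons between arms unless named. RNA-DNA distances were taken between the midpoints, with classes within 10 kb, from 10 kb to 1 Mb, over 1 Mb on 1 arm, and on another arm. No gene annotation in dm3 or hg19 was used here, so RNA sources were 1 kb windows of each strand, RNA classes were chromosomes of origin, and regions are named by coordinates. The named regions followed a rule written before the data were examined: the 15 windows with most distant contacts in each RICh-PET table, the 10 highest and 10 lowest ratios by the interval bound nearest to 1, the 10 S2 and 10 GM12878 control clusters with most PETs, and the 10 highest ChIRP-seq scores of each replicate, of which the text names the leading ones. The 10 highest control ATAC-seq peaks and the XHet region were chosen after their values were seen. The 13 gene lists fixed in advance could not be evaluated without an annotation, and the planned setting without ribosomal RNA was not run for the same reason. The ChIRP-seq input library and a dose of 100 µg/ml mentioned in the protocol were not analysed here.

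Ratios between the RICh-PET tables are ratios of shares of all PETs with exact conditional intervals, for windows with at least 20 PETs over both tables, and a window at 0 was set to a floor of 3 counts over the table. Shares carry 95% exact (Clopper-Pearson) binomial intervals and cluster numbers exact Poisson intervals; both cover counting error only, as reads are not independent molecules. On simulated windows with a true ratio of 4, 100% were called above 1, with a ratio of 2, 56%, and of 42320 windows left unchanged 3.19% were called. The simulated counts were Poisson, without repeated RNA positions or a spread between samples, so 3.19% is not the rate of false calls in the data. The roX2 window was the source in the standard table, among those with at least 100 distant contacts, with the largest share of them inside replicate 1 ChIRP-seq peaks.

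Peaks overlapped when they shared at least 1 bp. Control ATAC-seq peaks were those of control replicate 1 that overlapped replicate 2. Dose relations used Pearson's r and Spearman's rho over 8 libraries with exact permutation tests, two-sided, a threshold of 0.05, and Benjamini-Hochberg adjustment over 5 relations. The ChIRP-seq X share was compared with control ATAC-seq peaks by Fisher's exact test; its p is the one-sided hypergeometric tail on the log10 scale, as the p of replicate 1 is below the smallest number the software can hold, although a two-sided p had been planned. Overlaps were compared with 1000 shuffles within each arm, and peak densities with 100000 resamples. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

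Most alternative settings were written before the data were examined. Chosen after the data were seen were the chromosome 4 share in ATAC-seq, the relations among treated libraries only, matching by score and by score with width, the distance intervals, the main-chromosome ChIA-PET settings and those within and between fly arms or human chromosomes, the sum of PETs on main chromosomes, the ChIRP-seq background with each peak counted once, the RNA ends and the RNAPII contacts at anchors of at least 5 PETs, all sequences for the ChIRP-seq X share, the window next to the roX2 source, the strand side of local contacts, the shortened peak lists, the thinned GM12878 clusters, the spread of cluster ratios, and the XHet region.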

Results

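RNA-chromatin contacts, open chromatin and RNA polymerase II (RNAPII) contacts were measured in Drosophila S2 cells, an established cell line. RICh-PET joins an RNA fragment to the chromatin fragment beside it, so that each paired-end tag (PET) gives 1 RNA position with its strand and 1 DNA position. The standard table held 889263 PETs and the table from RNAPII-enriched chromatin 6140206 PETs, each pooled by the authors from 2 samples. Chromatin bound by roX2, a non-coding RNA of the complex that compensates the dosage of the male X chromosome, was mapped by ChIRP-seq in 2 samples, with 812 and 254 peaks. ATAC-seq, which marks accessible DNA, was done without RNase A and after 200, 400 and 800 µg/ml, with 2 libraries per dose and between 2575 and 8526 peaks per library. RNAPII ChIA-PET, which joins 2 DNA fragments held together with RNAPII, gave 213136 clusters in a pooled table of 2 S2 samples. Another 2 ChIA-PET libraries held S2 cells together with GM12878, an established human lymphoblastoid line, 1 without RNase A and 1 with 400 µg/ml. Fly coordinates are in build dm3, human coordinates in hg19, and both are 1-based.

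The comparison of the standard and RNAPII tables asks which RNA-chromatin contacts are found on RNAPII-bound chromatin. In both tables most contacts lay far from the RNA's own source. Of the PETs with both ends on the main arms X, 2L, 2R, 3L, 3R and 4, 48.7% of 836535 joined an RNA to another chromosome arm in the standard table, against 62.7% of 5208114 in the RNAPII table. Contacts within 10 kb of the source made up 19.9% and 18.5%, and contacts over 1 Mb away on the same arm 15.8% and 14.6%. By ratio, the class that differed most was the one from 10 kb to 1 Mb, and in percentage points the one on other arms. The class from 10 kb to 1 Mb held 15.6% in the standard table (95% exact binomial interval 15.5% to 15.7%) and 4.22% in the RNAPII table (4.20% to 4.24%), a ratio of 0.271.

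By distance on the same arm, the RNAPII share exceeded the standard share only below 1 kb, with a ratio of 1.28. The ratio then fell to 0.767 at 1 to 2 kb, 0.488 at 5 to 10 kb, and 0.168 at 100 to 200 kb, before reaching 0.410 at 500 to 1000 kb. Because of this crossing, the ratio for local contacts was 0.933 within 10 kb and 1.16 within 2 kb. Contacts on the RNA's own arm were 51.3% in the standard table, 2.5 times the 20.5% that the arm shares alone would give, and 37.3% in the RNAPII table, 1.87 times 20.0%. The samples are pooled in both tables, so these differences carry no replicate error, and the intervals cover counting error only.

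**Figure D1:**
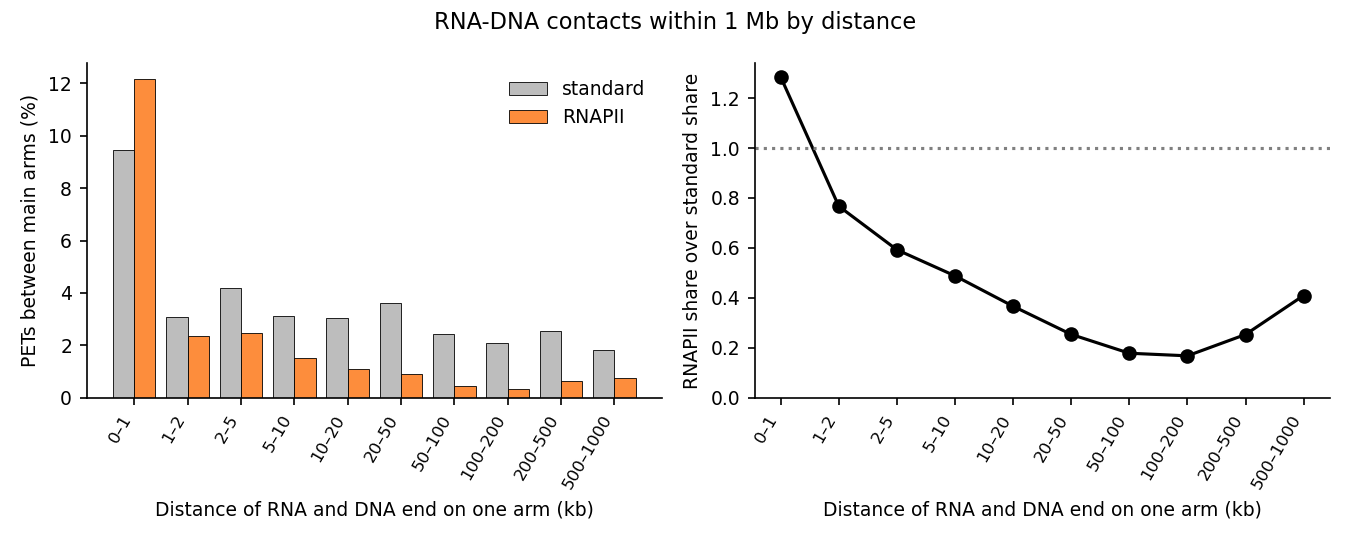
Share of PETs between main arms by the distance in kb of RNA and DNA end on 1 arm (bars, %; standard grey, RNAPII orange) and the ratio of the RNAPII share to the standard share (points; the dotted line marks 1). The RNAPII share is higher below 1 kb, at 1.28 times the standard share, and lowest relative to it at 100 to 200 kb, at 0.168 times.

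The RNA sources also differed between the tables. RNA from X made up 13.5% of the standard PETs and 17.9% of the RNAPII PETs, a ratio of 1.32 (95% exact interval 1.32 to 1.33). RNA from chromosome 4 rose from 0.830% to 1.04% (ratio 1.26, 1.23 to 1.29) and RNA from the heterochromatic sequences from 1.58% to 2.58% (ratio 1.64, 1.61 to 1.67). Autosomal arms gave 83.8% and 78.3%. Mitochondrial RNA fell from 0.271% to 0.125%, a ratio of 0.460 (0.439 to 0.482). These directions were the same among contacts between different arms or other sequences, and no test of samples was possible.

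Sources were then compared in 1 kb windows of the genome, each strand apart. The window with the most distant contacts, over 1 Mb away or on another sequence, was 3R:3300001-3301000 on the minus strand in both tables, with 6241 distant PETs in the standard table and 92145 in the RNAPII table, where its share was 2.13 times as high (2.07 to 2.18). Of its PETs, 98.5% and 98.9% were distant. The other leading sources differed in part. In the standard table they included 3R:7048001-7049000 on the plus strand (2683 distant PETs, RNAPII over standard 0.324), 2R:7782001-7783000 on the plus strand (2314, 0.653) and 2R:19727001-19728000 on the minus strand (2105, 0.516). The last 2 were also among the 15 leading RNAPII windows, with 10346 and 7483 distant PETs. Of the 15 leading standard windows, every one but the first had a lower share in the RNAPII table. These windows were picked by their standard values, which favours a lower share in the other table. In turn, the 15 leading RNAPII windows had higher shares in the RNAPII table, apart from 2R:7782001-7783000 and 2R:19727001-19728000. In the RNAPII table the sources after the first were 2R:1617001-1618000 on the minus strand (13875 distant PETs, ratio 5.47) and 3R:17123001-17124000 on the plus strand (11706, ratio 3.08). Of the 25391 PETs of this last window, 51.7% stayed within 10 kb of the source.

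Among 44421 windows with at least 20 PETs over both tables, the share of 10220 was higher in the RNAPII table, with a 95% exact interval above 1, and that of 7464 was lower. The highest folds were at 2L:3068001-3069000 on the plus strand (4970 RNAPII PETs against 4, ratio 180, 70.2 to 661), X:9228001-9229000 on the minus strand (2054 against 3, ratio 99.2, 33.9 to 481) and 2L:3046001-3047000 on the plus strand (2697 against 5, ratio 78.1, 33.4 to 241). At 2L:3068001-3069000 and 2L:3046001-3047000, 90.4% and 85.3% of the RNAPII PETs had their RNA end at 1 position within 2 bp. Neighbouring windows of X at 7529001-7530000 and 7530001-7531000 on the plus strand had ratios of 36.9 and 29.1. The window 3LHet:1227001-1228000 on the minus strand had 734 RNAPII PETs and 0 standard PETs. It was 35.4-fold higher against a floor of 3 counts, with an exact lower bound of 28.7. Ranked by the interval bound nearest to 1, the lowest was X:1700001-1701000 on the plus strand, with 152 standard PETs and 0 in the RNAPII table. It was 350-fold lower against the same floor, with an exact upper bound of the ratio of 0.00356. The next by this rank was X:16344001-16345000 on the minus strand, with 192 and 1 PETs (ratio 7.5e-04, 1.9e-05 to 0.00425). In both of these windows nearly all standard PETs, 100% and 99.5%, had their RNA end at 1 position within 2 bp. With the median ratio of the windows as the scale, 8704 were higher and 8813 lower, so the balance of both directions rests on the scale, while with at least 100 PETs 7010 were higher and 2030 lower.

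On the main arms the ChIRP-seq peaks of roX2 lay almost entirely on X, and over all sequences, unplaced ones included, the mean X share of the replicates was 83.7%. Of the main-arm peaks, 711 of 753 peaks of replicate 1 were on X, 94.4% (95% exact interval 92.5% to 96.0%), and 203 of 212 peaks of replicate 2, 95.8% (92.1% to 98.0%), a mean of 95.1% ± 0.942 (SD, n = 2). Accessible chromatin gave the background, since 17.2% of the 16569 entries in the 2 peak lists without RNase A were on X, most peaks being in both lists. The odds ratios against it were 81.4 and 108, and Fisher's exact test, taken one-sided, gave log10 p-values of -449 and -138. With each of the 7678 shared control peaks counted once, of which 17.1% were on X, the odds ratios were 82.3 and 110 and the log10 p-values -424 and -136. All of these p-values are over peaks, which are not independent replicates. Chromosome 4 held 0 peaks in both lists. The highest scores on the main arms in replicate 1 were at X:12654859-12656929 (214), X:11473181-11474936 (122), X:7214208-7217126 (103), X:15693785-15696327 (97.2) and X:12804243-12805923 (95.6). The scores are the authors' own. All of the 10 highest main-arm peaks of replicate 1 overlapped a peak of replicate 2, whose highest main-arm scores were at X:22349381-22349597 (57.7), X:12654869-12655633 (52.4) and X:11473251-11474594 (50.5).

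Of the 212 main-arm peaks in the shorter list, 198 overlapped the longer list, 93.4% (89.2% to 96.3%), against 3.19% on average and 7.08% at most when the peaks were shuffled within their chromosomes (permutation p = 0.001, the smallest value that 1000 shuffles can give). On X 197 of 203 peaks were shared, and on the other arms 1 of 9. In the other direction 18.5% of the longer list was shared.

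The RICh-PET tables gave a second view of roX2. The RNA window matched to the ChIRP-seq map was X:11473001-11474000 on the plus strand, the source whose distant contacts fell most often inside replicate 1 peaks, and it overlaps the ChIRP-seq peak at X:11473181-11474936. In the standard table, 278 of its 338 distant PETs were on X, 82.2% (77.7% to 86.2%), and in the RNAPII table, 791 of 1116, 70.9% (68.1% to 73.5%). Among the 439 other standard windows with at least 100 distant PETs, the median X share was 11.6% and the highest 21.7%. Among 8971 such RNAPII windows the median was 11.8% and the highest 27.7%, at X:10666001-10667000. The windows beside the roX2 source were left out of these others, and 1 of them, X:11474001-11475000, had 71.2% in the RNAPII table. Other windows on X had a median of 11.4% in the standard table, close to the 11.6% of windows on the autosomes. Inside replicate 1 ChIRP-seq peaks lay 15.4% of the distant contacts of the roX2 window in the standard table and 24.0% in the RNAPII table, against medians of 0.565% and 0.648% for the other windows. The window was chosen by this overlap in the standard table, so its excess there is fixed by the choice, and part of its X share follows from it; the RNAPII table did not decide the choice. Inside replicate 2 peaks, which mostly overlap those of replicate 1, lay 4.73% and 8.96%. Its share of all PETs was lower in the RNAPII table, with a ratio of 0.510 (0.454 to 0.574). This ratio covers only the 1 kb window, which was chosen in the standard table. The next window, X:11474001-11475000 on the plus strand, held 649 distant PETs in the RNAPII table and fewer than 100 in the standard table. The ratio of 0.510 thus does not describe roX2 RNA as a whole.

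**Figure D2:**
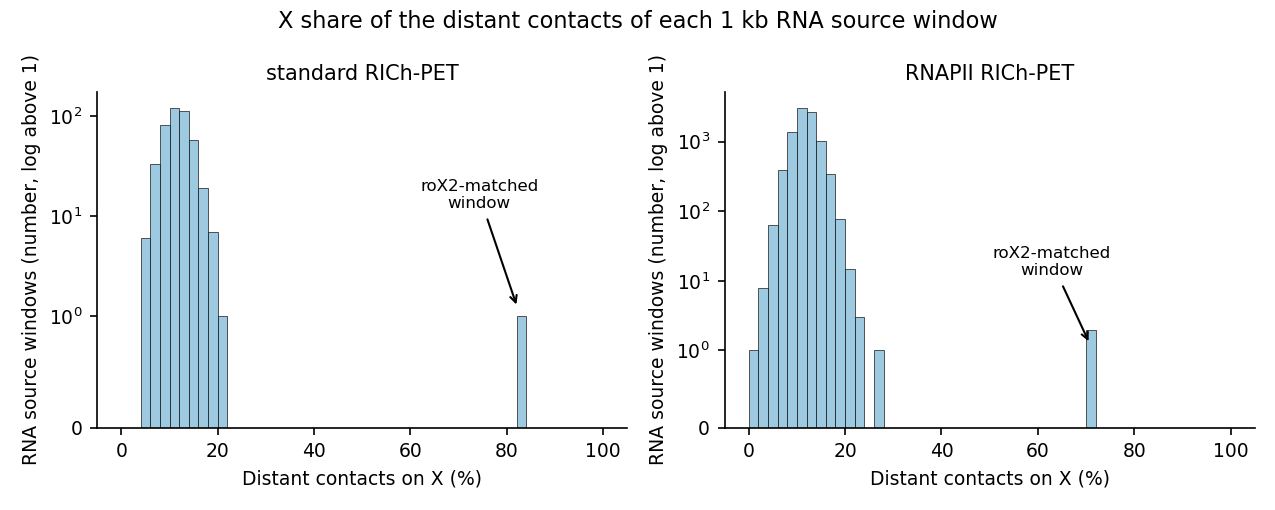
Number of 1 kb RNA source windows with at least 100 distant contacts (y axis, log scale above 1) by the share of those contacts on X (x axis, %), standard RICh-PET and RNAPII RICh-PET. The roX2-matched window stands at 82.2% in the standard table and at 70.9% in the RNAPII table, where its neighbour with 71.2% falls in the same bar; the highest other windows are at 21.7% and 27.7%.

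The ATAC-seq series asks what becomes of accessible chromatin when RNA is digested. Peaks on the main arms fell from 8284.5 ± 129 (SD, n = 2) without RNase A to 4251.5 ± 199 at 200 µg/ml, 3671.5 ± 1139 at 400 µg/ml and 2768.5 ± 357 at 800 µg/ml. The length they covered fell from 7305 ± 246 kb to 3107 ± 157 kb, 2555 ± 788 kb and 1642 ± 234 kb (n = 2 each). Of 7678 control peaks found in both control libraries, the libraries at 200, 400 and 800 µg/ml held 53.1% ± 2.39, 45.8% ± 13.8 and 34.3% ± 4.38 (SD, n = 2 each). The control libraries held 92.9% ± 1.73 of one another's peaks, a value on another base, since these 7678 peaks were chosen for being in both. In all 6 treated libraries 1750 of these peaks were found, and in none of them 2463.

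Against the dose, the peak number had Pearson's r = -0.827 (exact permutation p = 0.0222, n = 8) and Spearman's rho = -0.830 (exact p = 0.0198), two-sided. The covered length had r = -0.830 (exact p = 0.0222) and rho = -0.927 (exact p = 0.00318), while the share of control peaks found had r = -0.848 (exact p = 0.0139) and rho = -0.830 (exact p = 0.0198), with control values that are high by the choice of the peaks, so that for this share only the treated libraries give a test. Over the family of 5 relations, the X and chromosome 4 shares included, the Benjamini-Hochberg adjusted p of r was 0.0278 for these 3 and for the chromosome 4 share, and 0.0683 for the X share. Without the 2 libraries at 800 µg/ml, the farthest from the median dose, r was -0.894 for the peak number (exact p = 0.0667), -0.902 for the covered length (exact p = 0.0444) and -0.895 for the share found (exact p = 0.0667). Among the 6 treated libraries alone, r was -0.776 for the peak number (exact p = 0.111), -0.869 for the covered length (exact p = 0.0222) and -0.789 for the share found (exact p = 0.111), with adjusted p = 0.111 for the covered length over the 5 relations and exact p = 0.0667 for its rho. After this adjustment the calls for all 3 measures rest on the control libraries. Any RNase A against none lowered the mean peak number from 8284.5 to 3563.8, with exact permutation p = 0.0357, the smallest that 28 splits allow; 2 libraries against 2 cannot go below p = 0.333.

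**Figure D3:**
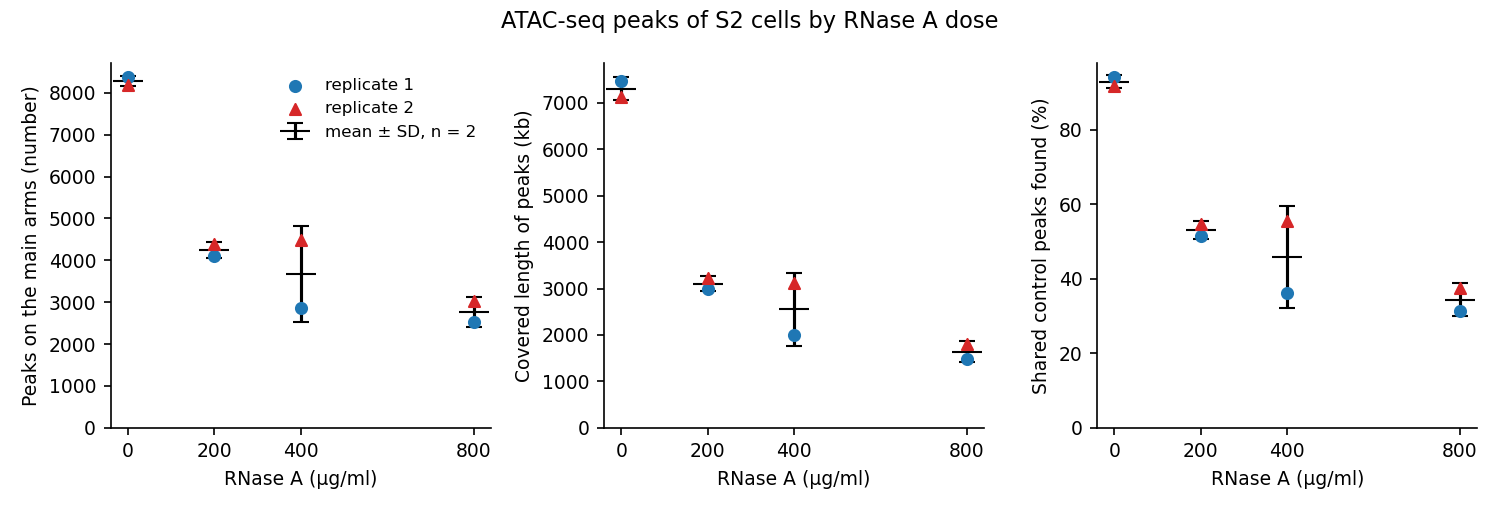
ATAC-seq peaks on the main arms (number), their covered length (kb) and the share of 7678 shared control peaks found (%), each against the RNase A dose in µg/ml; for the control libraries the share is that of one another's peaks. Points are libraries, horizontal bars and whiskers the mean ± SD of 2 libraries; the peak number falls from 8284.5 without RNase A to 2768.5 at 800 µg/ml, and the libraries differ most at 400 µg/ml.

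The peaks that were found again were mostly those with high control scores, which were also wide. At 800 µg/ml, control peaks divided into 4 equal groups by the authors' score were found in 75.8% ± 5.71 of cases in the highest group, 41.0% ± 7.07 and 15.9% ± 3.43 in the groups between, and 4.74% ± 1.33 in the lowest (SD, n = 2 each). Median widths were 1034.5 bp in the highest and 446 bp in the lowest group. In 4 equal groups by width, 57.6% ± 4.97 of the widest and 9.61% ± 2.03 of the narrowest were found (SD, n = 2 each). An overlap of 1 bp also favours wide peaks, so score and width were not separated here. The 10 control peaks with the highest scores, among them 2R:1613864-1615097 (score 520), 3L:639337-641492 (470) and 2L:13059972-13060658 (398), were present in all 8 libraries. Peaks shared by both libraries of a dose but absent from both control libraries numbered 14, 10 and 15 at 200, 400 and 800 µg/ml. Arms X, 2L, 2R, 3L and 3R kept between 33.1% and 36.0% of their control peaks at 800 µg/ml. Chromosome 4 kept 11.25% ± 1.77 of its 80 control peaks (n = 2), and its share of all peaks fell from 1.03% ± 0.00104 to 0.578% ± 0.0769, 0.412% ± 0.238 and 0.324% ± 0.00923 (n = 2 each; r = -0.830, exact p = 0.0139, n = 8; rho = -0.830, exact p = 0.0198; treated libraries only r = -0.670, exact p = 0.189), a relation added after its values were seen. The X share moved from 17.2% ± 0.158 to 16.5% ± 0.269 at 800 µg/ml, with r = -0.668 (exact p = 0.0683, n = 8) and rho = -0.683 (exact p = 0.0825). As a share of covered length the fall of X passed the threshold, with r = -0.855 (exact p = 0.00635), and among the upper part of each peak list, divided at the median score, its sign turned, with r = 0.432 (exact p = 0.278). Without replicate 1 at 400 µg/ml the fall also passed it, with r = -0.810 (exact p = 0.0270), as it did without replicate 2 at 800 µg/ml, with r = -0.773 (exact p = 0.0365).

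The mixed-cell ChIA-PET libraries ask what becomes of RNAPII-bound chromatin contacts after RNase A, with human cells beside the fly cells. S2 clusters numbered 28461 without RNase A (95% exact Poisson interval 28131 to 28794) and 6824 with 400 µg/ml (6663 to 6988), a ratio of 0.240. GM12878 clusters numbered 70071 (69553 to 70592) and 100063 (99444 to 100685), a ratio of 1.43. Relative to GM12878, S2 clusters were 0.168 times as many (0.163 to 0.173), which is 5.96-fold lower. This scale rests in large part on GM12878 clusters between chromosomes, which went from 37674 to 59837 (ratio 1.59), against a ratio of 1.24 within main chromosomes. Of the treated main-chromosome clusters, 4.04% in GM12878 and 32.0% in S2 were present in the control. Within 1 fly arm or human chromosome the relative value was 0.205, which is 4.89-fold lower, and between these 0.0541. With 1 library per condition there is no replicate check and no p-value, and the labels do not say whether the human cells were treated or in what ratio the cells were mixed.

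On the main arms nearly all strong S2 clusters had fewer PETs after RNase A, while most of the strongest clusters on unplaced sequence had more. Of 222 same-arm S2 clusters with at least 20 PETs, 221 had fewer PETs after RNase A and 1 had more, with 12242 PETs before and 3393 after, a ratio of 0.277. Of 132 such GM12878 clusters 69 had fewer, 57 more and 6 as many, with 5778 and 5941 PETs, a ratio of 1.03. The strongest main-arm cluster of S2 joined 3L:624873-641536 to 3L:636948-650267 and went from 1259 to 217 PETs. The cluster of 3L:605913-619567 with 3L:624051-635601 went from 774 to 245, that of 3L:8668379-8682838 with 3L:8677430-8694853 from 499 to 51, and that of 2R:1611951-1618720 with 2R:1622578-1638780 from 391 to 53. All of the 10 strongest main-arm S2 clusters had fewer PETs. In GM12878 the cluster of 6:26121666-26129707 with 6:26155394-26161562 had 248 and 257 PETs, and that of 17:38715528-38722951 with 17:38751020-38759744 had 185 and 141.

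Of all S2 control clusters, 6.71% (6.43% to 7.01%) overlapped a cluster after RNase A at both anchors, and of GM12878 control clusters 5.89% (5.72% to 6.07%). The share depended on the number of PETs. For clusters within 1 arm of S2 or 1 chromosome of GM12878 of 2, of 3 to 4, of 5 to 9, of 10 to 19 and of at least 20 PETs, it was 1.52%, 8.10%, 28.4%, 68.0% and 98.2% in S2 and 4.97%, 27.5%, 70.9%, 97.3% and 100% in GM12878. Anchors within 1 kb of one another raised the S2 share to 15.0%. Of the S2 control clusters on 1 main arm with at least 5 PETs, 93.4% (92.3% to 94.4%) were in the pooled table made from S2 cells alone, and of those with any number of PETs, 37.7% (37.1% to 38.4%).

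**Figure D4:**
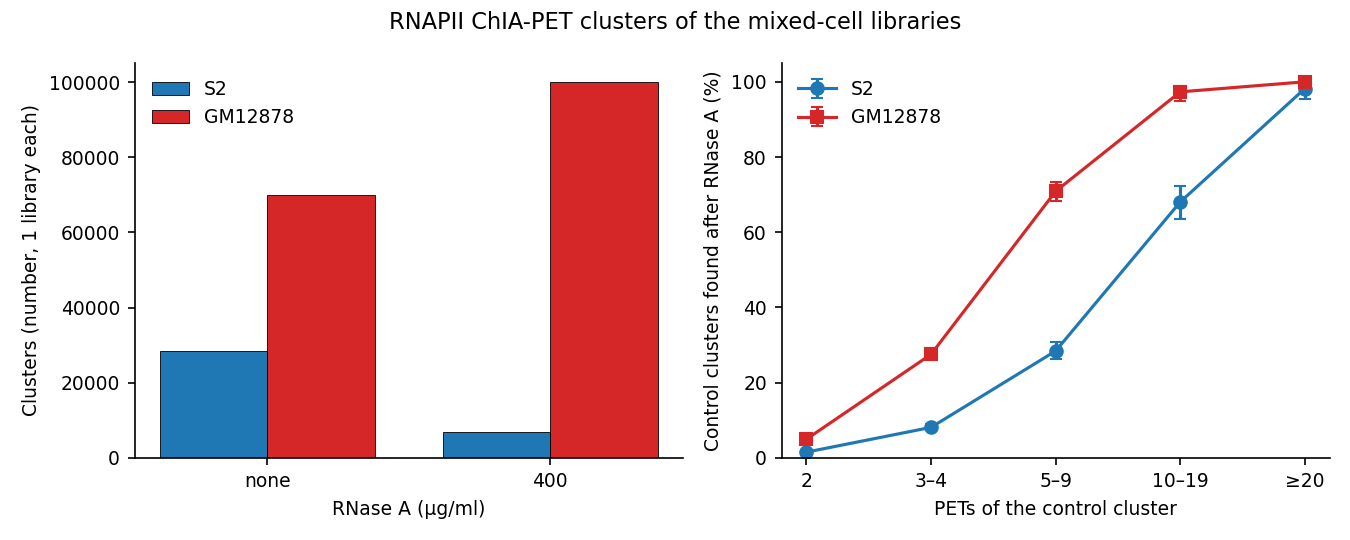
RNAPII ChIA-PET clusters of S2 (blue) and GM12878 (red) in the mixed-cell libraries without and with 400 µg/ml RNase A (bars, number of clusters, 1 library each), and the share of control clusters within 1 fly arm or 1 human chromosome found after RNase A (%) by their number of PETs (points, with 95% exact binomial intervals). S2 clusters go from 28461 to 6824 and GM12878 clusters from 70071 to 100063.

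RNA contacts were then set beside accessible regions and RNAPII contacts. Control ATAC-seq peaks held 3.53 times as many distant DNA ends of the standard table as the same peaks shuffled within their arms, and 7.58 times as many of the RNAPII table (permutation p = 0.001 in both, the smallest that 1000 shuffles can give). The 1975 control peaks found in both libraries at 800 µg/ml had 19.2 ± 12.1 distant standard PETs per kb, and the 4379 found in neither 14.0 ± 9.39 (SD over peaks). The difference of 5.25 PETs per kb had a permutation p of 1.0e-05, two-sided, the smallest that 100000 resamples can give, over peaks, which are not independent replicates. Among 945 peaks of each group drawn to have like control scores, a matching chosen after the data were seen, the difference was -0.0614 (permutation p = 0.885). Their median widths still differed, at 1096 and 752 bp. For RNAPII contacts the densities were 358 ± 424 and 170 ± 231 PETs per kb, and peaks matched on both score and width still differed in their means, by 54.0 PETs per kb (permutation p = 0.00103), with medians of 164 and 160 PETs per kb.

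Anchors of the S2 RNAPII clusters also held more RNA contacts than shuffled anchors. The 32416 merged anchors held 285245 distant DNA ends of the standard table, 1.85 times the mean of 1000 shuffles within their arms (permutation p = 0.001, the smallest value possible), and 2.88 times for the RNAPII table. Anchors of clusters with at least 5 PETs held 2.36 and 4.38 times as many. RNA sources lay there too: anchors of clusters with at least 5 PETs held 2.12 times as many RNA ends of distant contacts as shuffled anchors in the standard table and 2.95 times in the RNAPII table. Both the RNAPII table and the anchors come from chromatin enriched for RNAPII, so an excess of its DNA ends at anchors follows from the design. Shuffled anchors were not matched for accessibility, and control ATAC-seq peaks alone held 3.53 and 7.58 times as many distant DNA ends as shuffled peaks.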

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

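The tests of unplaced sequence, of the XHet region, of the spread of cluster ratios and of thinned GM12878 clusters were chosen only after the result was seen; the thinning test of S2 clusters was written before.

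S2 and GM12878 clusters moved in opposite directions in the mixed-cell libraries, which is what brought them here: the number after RNase A was 0.240 times that without it in S2 and 1.43 times in GM12878, and this difference was not tested, as each condition had 1 library. The rise in GM12878 lay mostly in weak clusters, and it was larger between main chromosomes (ratio 1.59) than within them (1.24). The GM12878 ratio was 1.17 from 3 PETs, 1.13 from 5 PETs and 1.03 for the PETs of clusters with at least 20, against 0.228, 0.240 and 0.277 in S2. A candidate explanation without any RNA effect is that the treated library held fewer S2 PETs, and thinning the control clusters by the ratio of the strong ones, 0.277, left 53.7% (51.2% to 55.9%) of clusters of 5 to 9 PETs, -25.2 percentage points from the 28.4% found, but without the losses that occur between any libraries. With the treated GM12878 clusters thinned to the S2 ratio, 33.2% (31.5% to 35.1%) of GM12878 clusters of that size were found, a difference of -4.82 for S2, and this range lies above the S2 interval of 26.2% to 30.7%, which by the criterion first set speaks against thinning as the whole cause for this size. For clusters of 10 to 19 PETs the 71.2% (67.6% to 74.9%) overlapped the 68.0% (63.4% to 72.4%) in S2, and the criterion was widened to every size after these values were seen, because the ranges come from simulated draws and leave out the sampling of clusters. Beyond counting error the SD of the log ratios of strong clusters was higher in S2 than in GM12878 by 0.0831 (bootstrap 95% interval -0.0392 to 0.195), so thinning and a loss of particular S2 contacts cannot be told apart by these tests, and the mixing ratio, the treatment of the human cells and a biological effect of RNA on S2 contacts stay open.

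On unplaced fly sequence, the 25 mixed-cell clusters with at least 100 PETs went from 11733 to 14385 PETs with 22 of them rising, and 0 of the 25 were found in the pooled table from S2 cells alone, where human reads placed on fly sequence cannot occur. However, that table held 768 unplaced clusters of at most 87 PETs and 0 mitochondrial clusters. The S2 clusters of the mixed-cell control included 4005 unplaced and 17 mitochondrial ones. The absence of the 25 thus cannot tell human reads from another difference between the tables. On the main chromosomes only, without unplaced, heterochromatic and mitochondrial sequence, the S2 ratio relative to GM12878 was 0.170.

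Outside the main arms, 42 roX2 ChIRP-seq peaks of replicate 1 and 32 of replicate 2 lay on unplaced sequence, led in both by Uextra:22164602-22164987 (score 1084) and Uextra:22164606-22164987 (score 1169). XHet held 11.8% of the DNA ends in the RNAPII RICh-PET table, against 2.34% in the standard table, most of them in XHet:189001-196000. That region, with 11.5% of the RNAPII and 2.16% of the standard DNA ends, is left out of the comparisons between main arms. The shares of RNA sources, the window ratios and the roX2 X share count PETs on every sequence, and so include it. No explanation of these signals was tested.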

How the results depend on the processing

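Settings with treated libraries only, matched scores, and parts of ChIA-PET chromosomes were chosen only after the result was seen. Of 162 alternative values, 110 kept their direction and their side of the threshold or stayed within their spread, 38 moved, 7 fell short of the threshold, 3 newly passed it and 4 reversed.

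Leaving out each library in turn, r ranged from -0.869 to -0.781 for the ATAC-seq peak number, -0.874 to -0.785 for the covered length, -0.884 to -0.809 for the share of control peaks found and -0.900 to -0.783 for the chromosome 4 share, each with exact p below the threshold. For the X share r ranged from -0.810 to -0.549, and it passed the threshold without replicate 1 at 400 µg/ml or replicate 2 at 800 µg/ml and as a share of covered length (-0.855); it reversed in the upper part of each list by score (0.432), and the cause was not tested. With replicate number as a block, r was -0.834, -0.833, -0.858, -0.693 and -0.834 for number, length, share found, X and chromosome 4. Among treated libraries only, with fewer samples, r was -0.776, -0.789 and -0.670 for number, share found and chromosome 4 (exact p = 0.111, 0.111 and 0.189). With an equal number of peaks per library the share found reversed (0.304), which the setting fixes by its construction. Any RNase A against none differed by -4903 to -4511 peaks, with exact p = 0.143 without either control library (-4629 and -4812) and 0.0625 in the block (-4721), the smallest that these designs allow. The ChIRP-seq X share was 94.4% to 95.8% by replicate and 83.7% over all sequences.

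With all sequences the RICh-PET distance ratios were 0.838, 0.245, 0.831 and 1.33, from local to other arms or sequences. With a local limit of 2 kb the local ratio reversed to 1.16 and the middle one was 0.360, because on the same arm the RNAPII share is higher only below 1 kb. With contacts on other arms or sequences only, the source ratios were 0.949 for autosomes, 1.19 for X, 1.12 for chromosome 4, 1.45 for heterochromatic and 0.387 for mitochondrial RNA. With at least 100 PETs summed over both tables, a filter in which the larger RNAPII table weighs most, 2030 windows were lower and 7010 higher, and the cause was not tested. The roX2 X share was 70.9% in the RNAPII table; the cause was not tested.

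The S2 ratio relative to GM12878 was 0.195 from 3 PETs, 0.211 from 5 PETs, 0.252 as a sum of PETs (0.163 on main chromosomes only, as unplaced sequence held 17597 of the 35646 treated S2 PETs), 0.240 unscaled, 0.213 from 10 kb, 0.205 within 1 fly arm or human chromosome, 0.189 there from 5 PETs and 0.0541 between these, all below 1. The S2 share found was 15.0% within 1 kb, 44.1% from 5 PETs and 7.12% from 10 kb. The density difference at kept ATAC-seq peaks reversed among score-matched peaks (-0.0614) and was 0.333 with width matched too, so in the standard table it goes with the score; in the RNAPII table a difference of means of 54.0 was left. The number of PETs limits the window ratios: ratios of 2 were called in 56% of simulated windows.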

Other observations

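The tests of strand side, of the XHet region of contact density at anchors and of shortened peak lists were chosen only after the result was seen; those of peak ranking, of chromosome 4 and of distance between anchors were written before.

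Local RNA contacts differed in orientation between the RICh-PET tables. Among contacts from over 1 kb to 10 kb from the RNA source on main arms, the DNA end lay on the downstream side of the RNA's strand in 49.1% of standard PETs (48.8% to 49.5%) and in 76.4% of RNAPII PETs (76.3% to 76.5%). Over all local contacts up to 10 kb, the values were 46.0% (45.7% to 46.2%) in the standard table and 66.8% (66.7% to 66.9%) in the RNAPII table. Mitochondrial RNA had 18.96% of its contacts on mitochondrial DNA in the standard table (17.4% to 20.6%) and 9.58% in the RNAPII table (8.93% to 10.3%), against 0.342% and 0.242% for nuclear RNA. The X-linked ATAC-seq control peaks inside replicate 1 roX2 peaks were found at 800 µg/ml in 28 of 132 cases, 21.2% (14.6% to 29.2%), and those outside in 292 of 1178, 24.8% (22.3% to 27.4%); the peaks inside had lower control scores (median 16 against 21) and were narrower (615 against 806 bp).

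The 7 kb region XHet:189001-196000 held 19169 DNA ends of the standard table and 708474 of the RNAPII table, a share 5.35 times as high. Its 1 kb windows did not move alike. From the standard to the RNAPII table, XHet:194001-195000 went from 0.435% to 5.41% of all DNA ends and XHet:191001-192000 from 0.392% to 4.21%. In contrast, XHet:189001-190000 fell from 0.218% to 0.00879% and XHet:192001-193000 from 0.224% to 0.0171%. In the standard table, 96.8% of the DNA ends in the region were joined to RNA from other sequences, and the mix of sources differed from the rest of the genome. RNA of 3R:7049001-7050000 on the plus strand made up 2.33% of its contacts against 0.268% elsewhere, and RNA of 3R:3300001-3301000 on the minus strand 0.178% against 1.09%. In the RNAPII table both were lower in the region than elsewhere, with ratios of 0.342 and 0.198. The ATAC-seq and ChIRP-seq lists had 0 peaks in the region, and 0 clusters of the pooled S2 ChIA-PET table lay there.

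The fall of ATAC-seq peaks with RNase A could come from lower depth or signal alone, which would thin 1 common ranking of peaks. The equal-sized lists of 2516 strongest peaks of both libraries at 800 µg/ml shared 74.0% with one another and 64.6% to 68.0% with the control lists, 6.0 percentage points above the highest of these, and 75.1% to 78.7% with lists at lower doses. With every list shortened to its 1000 strongest peaks the excess was 20.1 percentage points (72.2% against 48.6% to 52.1%), where the criterion set for a common ranking was no excess. Median scores were 6 in both libraries at 800 µg/ml and 21 and 16 in the controls, and equal scores were ordered by width. Treated lists may therefore agree through ties, so the lists cannot decide whether thinning is the whole cause. Of 2007 peaks shared by both libraries at 800 µg/ml, 15 (0.747%) were absent from both controls, as thinning would also give. Depth, how scores depend on it, and differences in tagmentation after permeabilisation and RNase stay open. The loss of RNA itself is the biological explanation the design names, untested apart from these. Peaks on chromosome 4, found in both 800 µg/ml libraries in 4 of 80 cases (5%, 1.38% to 12.3%), lay below the 17.4% of other-arm peaks matched on control score and width.

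RNA and DNA ends of 1 PET also met at both anchors of the same RNAPII cluster. Over 10348 clusters of the pooled S2 table with at least 5 PETs, PETs joining both anchors were 3.52 times as many as PETs to mirrored positions at the same distance in the standard table (bootstrap 95% interval 3.17 to 3.90) and 2.94 times in the RNAPII table (2.44 to 3.53), which distance alone does not give. The bootstrap drew clusters as if independent, although clusters of at least 5 PETs merged to 7251 anchors. Its intervals, here and below, may therefore be too narrow. Weighted by the RNA ends at the other anchor, anchors held 2.08 times (standard) and 3.62 times (RNAPII) the distant DNA ends of mirrored positions. Divided by that density the ratios were 1.69 (1.52 to 1.92) in the standard table and 0.810 (0.644 to 1.01) in the RNAPII table. Only distant DNA ends were counted, so a higher density of nearer contacts at anchors was not divided out. Distant density may thus be enough for the RNAPII table, while in the standard table an excess over it is left. That this excess follows the RNAPII contacts themselves is only a hypothesis from the same data, which these values cannot decide.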
